A study of Mus musculus with 14 samples.

How the data were processed

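Gene expression was measured on 14 Affymetrix whole-transcript arrays, 1 per RNA sample, hybridised with biotin-labelled cDNA made from total RNA, per the labels' protocols. The cells were mouse embryonic fibroblasts of the ICR strain, kept in medium for mouse embryonic stem cells. They were transduced with SKO and an empty Flag vector, SKO and HDAC7, SKO and MEF2C, or GFP, and lysed at day 6 or day 10. Feeder cells were removed before lysis, per the labels' protocols. Each SKO group had 2 arrays per day, which the labels number as experiments 1 and 2. The GFP group had 1 array per day. Nothing in the labels says that the experiments were separate cultures, so p-values measure only the spread between these arrays, which may be technical. A free-text description repeated on all 14 arrays names a pre-iPSC sample and was not used to assign groups.

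The deposited values are log2 expression values per probe set, and RMA and Partek are the tools named in the submitters' processing notes, without versions. The genome build was not given in the sources used here, so no coordinates are printed. The deposited log2 values were used as they stood, with no further normalization and no filter on dim probe sets. No detection calls were used here. The medians of the arrays lay between 5.68 and 5.76. The number of arrays limits the precision. No pair of replicate arrays was identical: the SD of their differences over all probe sets ranged from 0.120 to 0.172, and the pair of SKO+Flag arrays at day 10 was the widest.

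The table held 28815 probe sets. The platform annotation gave 1 gene symbol for 21780 of them, several for 1605 and no name here for 5430. Symbols were checked through Entrez IDs against a RefSeq gene table of assembly GRCm38.p6, used for names alone: 21689 probe sets matched, 91 did not and kept their annotated symbol, and the check changed 0 symbols. Probe sets with several genes or no name were left out. A gene with more than 1 probe set (998 genes) was represented by the probe set with the highest mean over the 14 arrays, which left 19935 genes. Whether probes of related genes, such as Akr1c14 and Akr1c18, cross-hybridise was not checked, so their values are uncertain.

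Differences were tested in R 4.3.3 with limma 3.58.1. One group-means model (lmFit, eBayes) was fitted to all 14 arrays in 8 groups (vector by day), so that all groups shared 1 estimate of the spread per gene, with 6 residual degrees of freedom and 4.71 prior degrees of freedom. The GFP groups, with 1 array each, are assumed to vary like the others. Comparisons were SKO+HDAC7 with SKO+Flag, SKO+MEF2C with SKO+Flag, SKO+Flag with GFP (each per day and as the mean of both days), day 10 with day 6 within each SKO group, the change of the HDAC7 and MEF2C effects between days, and SKO+HDAC7 with SKO+MEF2C. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Differences are on the log2 scale with their standard error (SE), and folds are taken from them.

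The gene lists, the model, the rule for named genes and the alternatives below were fixed before the data were examined. Of 23 lists with 460 entries, 428 entries were measured. They cover the transduced factors, the class IIa HDAC and MEF2 family, epithelial and mesenchymal genes, extracellular matrix, myofibroblast contractile genes, TGF-beta signalling, BMP response, pluripotency, MEF2 targets and striated muscle, cell cycle, p53 and senescence, interferon response, inflammatory and secreted genes, glycolysis, cholesterol synthesis, stress response, and markers of macrophages and blood, endothelium, neural and glial cells, keratinocytes, endoderm and trophoblast, and fat and cartilage. The other 22 lists were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists of a comparison, and again with the correlation estimated from the data. Transduced genes were left out of these tests.

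Named genes were the transduced factors; the 10 genes with the largest change in each direction among those called and of 1 sign in every pair of arrays (5 in each direction for the day-specific, interaction and HDAC7 with MEF2C comparisons); and up to 4 members of each list, by size of change among called members. Alternatives were an intensity-dependent robust prior, array weights, a fit to the compared groups alone, quantile normalization, median centring, the mean over a gene's probe sets, genes above the median level, a difference of at least 1, the experiment number as a replicate block (for both days together or within each day), and leaving out each array. A block with crossed numbers was added later. The procedure was tested on simulated data for 19935 genes in 10 draws. For the HDAC7 effect averaged over days it recovered 78.4% of genes changed by 0.3 and 99.6% of those changed by 0.6, with 6.9 false calls on average. For day 6 alone it recovered 29.6% and 97.6%. The simulated noise was drawn for each gene independently from the fitted spread. It holds no noise shared across genes or cultures, so the false calls do not carry over to the real lists.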

Results

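The arrays compare fibroblasts that received SKO with an empty vector (Flag), with HDAC7 or with MEF2C, and fibroblasts that received GFP. The labels do not spell out SKO, which commonly stands for the reprogramming factors Sox2, Klf4 and Oct4 (Pou5f1). HDAC7 is a class IIa histone deacetylase, and MEF2C is a transcription factor of the MEF2 family, to which class IIa deacetylases bind. The series asks how expression differs when HDAC7 or MEF2C is added to SKO. There were 2 arrays for each SKO group at day 6 and at day 10, and 1 GFP array at each day, 14 in all. Replicate arrays correlated at 0.995 to 0.997 over all probe sets. The first principal component held 52.1% of the variance and set the GFP arrays (49.7 and 54.6) apart from the SKO arrays (-19.3 to 2.51). The second held 19.7% and ran from -19.8 and -19.4 for SKO+MEF2C at day 6 to 23.9 and 23.4 for SKO+HDAC7 at day 10.

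The added factors were found on the arrays that carry their labels. Hdac7 was 19.4-fold higher in SKO+HDAC7 than in SKO+Flag (log2 difference 4.28 ± 0.06 SE, limma adjusted p = 1.6e-11), higher in 4 of 4 pairs of arrays. Mef2c was 8.41-fold higher in SKO+MEF2C than in SKO+Flag (3.07 ± 0.07, adjusted p = 3.9e-09), also in 4 of 4 pairs. Pou5f1 was at least 108-fold higher in SKO+Flag than in GFP (6.75 ± 0.07, adjusted p = 2.4e-13); this is a lower bound, since its GFP values lie below the medians of those arrays and are not shown to be above background. Sox2 (0.16 ± 0.07, limma adjusted p = 0.082) and Klf4 (0.17 ± 0.07, limma adjusted p = 0.081) did not pass the test in that comparison. Hdac7 was lower there (-0.47 ± 0.07, limma adjusted p = 0.00033), and Mef2c did not pass (0.10 ± 0.09, limma adjusted p = 0.42). At day 10 alone the Klf4 difference was 0.32 ± 0.10 (limma adjusted p = 0.035), from 2 SKO+Flag arrays against 1 GFP array, whose spread is taken from the other groups. In SKO+Flag, Klf4 lay at 8.85 and 9.05 at day 6 and at 9.03 and 8.93 at day 10. On the GFP arrays it lay at 8.93 at day 6 and 8.66 at day 10, so the day 10 difference rests on that lower GFP value. Pou5f1, Sox2 and Klf4 did not pass the test between SKO+HDAC7 and SKO+Flag (limma adjusted p of 0.45, 0.38 and 0.80) or between SKO+MEF2C and SKO+Flag (0.15, 0.59 and 0.38). Pou5f1 was higher in SKO+HDAC7 than in SKO+MEF2C by 0.21 ± 0.05 (adjusted p = 0.017).

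**Figure D1:**
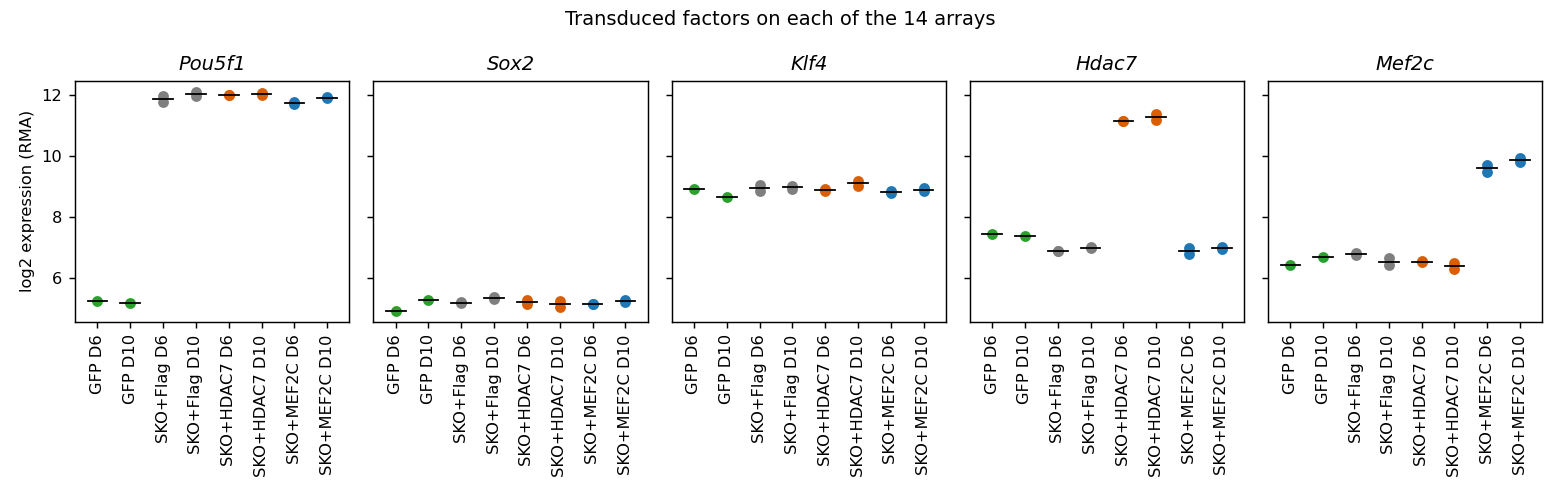
The log2 expression of Pou5f1, Sox2, Klf4, Hdac7 and Mef2c on each of the 14 arrays (points), with a line at the mean of each group. Pou5f1 lies at 5.18 and 5.24 on the GFP arrays and between 11.7 and 12.1 on the SKO arrays, Hdac7 lies above 11 only on the SKO+HDAC7 arrays, and Mef2c lies above 9 only on the SKO+MEF2C arrays.

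Matrix, mesenchymal and contractile genes were lower and cell cycle and cholesterol synthesis genes higher in SKO+Flag than in GFP. Among the genes raised most were Akr1c18, a steroid-metabolising aldo-keto reductase (5.90 ± 0.05), Gpr50 (5.80 ± 0.07), Aldh3a1, an aldehyde dehydrogenase (5.52 ± 0.06), Sbspon (5.03 ± 0.06) and Trh, the precursor of thyrotropin-releasing hormone (4.94 ± 0.08). The GFP values of these raised genes also lie below the array medians, so that their differences are lower bounds. Those lowered most were Ogn, a small leucine-rich proteoglycan (-3.56 ± 0.13), Dlk1 (-3.26 ± 0.10), Ptn (-2.87 ± 0.11) and Svep1 (-2.82 ± 0.08). Each of these had a limma adjusted p of 5.6e-09 or less. The rule for naming them required 1 direction in 4 of 4 pairs, which reuse 1 GFP array per day. Of 19935 genes, 7118 differed as the mean of both days (4 arrays against 2), 3497 higher and 3621 lower, and 903 differed by at least 1 on the log2 scale.

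Extracellular matrix genes fell most evenly with SKO: 22 of 24 measured members fell and 0 rose (22 and 0 adjusted over the list alone; camera adjusted p = 2.2e-13). Lum was at -2.56, Lox, which cross-links collagen, at -2.47, Col3a1 at -2.25 and Postn at -2.17. Of 25 mesenchymal genes 18 fell and 2 rose (18 and 3 adjusted over the list alone; camera adjusted p = 2.4e-08), with Pdgfra down by -2.25 and Snai2, a repressor of E-cadherin, by -1.64. Of 15 myofibroblast contractile genes 13 fell and 0 rose (13 and 0 adjusted over the list alone; camera adjusted p = 4.4e-11), among them Cnn1 (-2.52) and Tagln (-1.86). Of 29 cell cycle genes 24 rose and 1 fell (26 and 1 adjusted over the list alone; camera adjusted p = 5.9e-12), with Mki67 at 1.26 and the ribonucleotide reductase subunit Rrm2 at 1.05. Of 15 cholesterol synthesis genes 13 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 2.4e-08), with Idi1 at 1.01 and Fdft1 at 0.80. These 5 lists also passed with an estimated correlation (adjusted p of 0.0047 to 0.024).

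Other lists moved in part. Of 29 epithelial genes 8 rose and 3 fell (8 and 3 adjusted over the list alone), led by the protease inhibitor Spint2 (2.31 ± 0.06), the desmosomal Dsp (1.93 ± 0.08) and the adhesion molecule Epcam (1.90 ± 0.08). The camera adjusted p was 0.038, and the adjusted p was 0.42 with an estimated correlation; without SKO+Flag day 6 replicate 2 or day 10 replicate 1 it was 0.0997 or 0.083 at the preset correlation. Of 18 p53 and senescence genes 13 fell and 3 rose (14 and 4 adjusted over the list alone; camera adjusted p = 0.0042, adjusted p = 0.12 with an estimated correlation), with Plk2 at -1.59 and Perp at 2.22. Of 16 stress response genes 11 fell and 2 rose (12 and 2 adjusted over the list alone; camera adjusted p = 0.0013, adjusted p = 0.070 with an estimated correlation), with Trib3 at -1.58 and Hmox1 at -1.21. Of 28 pluripotency genes 8 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.22), led by L1td1 (1.99 ± 0.07) and Tfcp2l1 (1.62 ± 0.07). The list had a median of -0.05 and a mean of 0.16, and among genes above the median level its camera adjusted p was 0.0053. TGF-beta signalling had 10 lower and 5 higher of 19 (11 and 6 adjusted over the list alone; camera adjusted p = 0.056). Its camera adjusted p was 0.026 after quantile normalization and 0.027 after median centring. BMP response had 4 higher and 5 lower of 12 (4 and 6 adjusted over the list alone; camera adjusted p = 0.94), with a median of -0.11 and a mean of 0.06.

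Each day sets 2 SKO+Flag arrays against 1 GFP array, so these tests borrow the spread of GFP from the other groups. At day 6 alone 4798 genes passed (2638 higher, 2160 lower), with Akr1c18 at 6.30 and Ogn at -3.08. At day 10, 5359 passed (2726 higher, 2633 lower), with Dlk1 at -4.38, Dpt at -3.81 and Igfbp2 at -3.53. At day 10 all 24 extracellular matrix genes were lower (24 adjusted over the list alone; camera adjusted p = 1.1e-20, adjusted p = 0.0014 with an estimated correlation). A fit to the SKO+Flag and GFP arrays of day 10 alone called 3012 genes. Whether the effect of SKO differed between days was not tested.

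HDAC7 lowered matrix and contractile genes and raised keratinocyte, cell cycle and interferon genes on top of SKO. The largest rises after Hdac7 were Krt19, a keratin of simple epithelia (1.48 ± 0.05, 2.79-fold), Cd34 (1.23 ± 0.06), Esm1 (1.14 ± 0.10), the lipoprotein lipase Lpl (1.13 ± 0.08), Npy (1.12 ± 0.07) and its receptor gene Npy2r (1.10 ± 0.09). The largest falls were Akr1c14 (-1.61 ± 0.10), Frem2 (-1.51 ± 0.07), the adhesion molecule Vcam1 (-1.28 ± 0.05), Col8a1 (-1.27 ± 0.08) and Mgp, the matrix Gla protein (-1.24 ± 0.06). All of these had limma adjusted p values of 3.4e-05 or less, and 1 direction in 4 of 4 pairs, which the rule for naming them required. As the mean of both days (4 arrays against 4), 2171 genes differed, 963 higher and 1208 lower, and 37 differed by at least 1. Median centring of the arrays gave 637 higher and 1519 lower, so the split between directions rests on the scaling.

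Under HDAC7, 17 of 24 extracellular matrix genes fell and 3 rose (17 and 4 adjusted over the list alone; camera adjusted p = 9.3e-13). Lox fell by 1.13, Col11a1 by 0.96 and Bgn by 0.89, whereas Col3a1 rose by 0.88 ± 0.05. Of 15 myofibroblast contractile genes 8 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 4.8e-11), among them the smooth muscle genes Myl9 (-1.17), Tagln (-1.10) and Acta2 (-0.75). TGF-beta signalling had 10 lower and 0 higher of 19 (10 and 1 adjusted over the list alone; camera adjusted p = 1.7e-09), with Ccn2 at -0.90, the ligand Tgfb2 at -0.85 and Ltbp2 at -0.78. With an estimated correlation the adjusted p was 0.0054 for matrix, 0.038 for contractile genes and 0.044 for TGF-beta signalling. Of 25 mesenchymal genes 12 fell and 3 rose (13 and 3 adjusted over the list alone; camera adjusted p = 6.1e-05, adjusted p = 0.055 with an estimated correlation). Pdgfrb was lower by -0.48 ± 0.05, and Cdh2, which encodes N-cadherin, was higher by 0.48 ± 0.04. BMP response had 3 lower and 1 higher of 12 (3 and 1 adjusted over the list alone), with Bmp2 at -0.81. Its camera adjusted p was 0.035, the adjusted p was 0.10 with an estimated correlation, and quantile normalization gave 0.107; it also lost its call without any 1 of 4 arrays.

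Of 29 epithelial genes 10 rose and 0 fell under HDAC7 (15 and 0 adjusted over the list alone; camera adjusted p = 1.8e-07, adjusted p = 0.055 with an estimated correlation). Beside Krt19 they included Cdh1, which encodes E-cadherin (0.56 ± 0.08), and Epcam (0.52 ± 0.07). Keratinocyte markers had 8 higher and 0 lower of 15 (9 and 0 adjusted over the list alone; camera adjusted p = 1.4e-06), led by Pkp1 (0.87), Krt14 (0.73) and Krt6a (0.62). Cell cycle genes had 10 higher and 0 lower of 29 (17 and 0 adjusted over the list alone; camera adjusted p = 7.4e-09), with the replication licensing gene Mcm2 at 0.38, Mcm3 at 0.32 and Pcna at 0.31. Interferon response had 8 higher and 0 lower of 22 (9 and 0 adjusted over the list alone; camera adjusted p = 9.7e-07), with Oas2 at 0.51 and Usp18 at 0.41. Neural and glial markers had 7 higher and 0 lower of 16 (7 and 0 adjusted over the list alone; camera adjusted p = 0.0035), with the neurofilament gene Nefl at 1.09. With an estimated correlation the adjusted p was 0.038 for keratinocyte markers, 0.044 for cell cycle, 0.038 for interferon response and 0.046 for neural markers. Pluripotency genes had 5 higher and 0 lower of 28 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00064, adjusted p = 0.17 with an estimated correlation), with Nr0b1 and Sall1 both at 0.43. MEF2 targets and striated muscle genes had 2 higher and 2 lower of 32 (2 and 2 adjusted over the list alone; camera adjusted p = 0.53). In the class IIa HDAC and MEF2 family Hdac5 fell by 0.61 (1 higher, Hdac7 itself, and 1 lower of 7; 2 and 2 adjusted over the list alone; camera adjusted p = 0.20).

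At day 6 HDAC7 changed 914 genes (363 higher, 551 lower; 235 and 708 after median centring). Cd34 (1.41) and Nefl (1.39) were among the largest rises, and Akr1c14 (-1.94) and the tissue factor gene F3 (-1.15) among the largest falls. At day 10 it changed 1450 (663 higher, 787 lower; 465 and 856 after median centring), with Krt19 at 1.76, Ehf, an epithelial transcription factor, at 1.29 and Vcam1 at -1.66. Called at both days in 1 direction were 137 higher and 318 lower genes, against 12.1 and 21.8 for independent lists. At day 6, leaving out SKO+Flag replicate 1 or 2 of that day gave 338 or 437 genes, and leaving out SKO+HDAC7 replicate 1 or 2 gave 293 or 460. At day 10, leaving out SKO+HDAC7 replicate 1 or 2 gave 793 or 785, and fits to the compared groups alone called 375 genes at day 6 and 501 at day 10.

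MEF2C raised contractile, mesenchymal and BMP genes and lowered cell cycle and interferon genes on top of SKO. The largest rises after Mef2c were Anxa10, an annexin (2.27 ± 0.06, 4.83-fold), the fatty acid binding protein gene Fabp3 (1.52 ± 0.07), Akr1c14 (1.38 ± 0.10), C1qtnf3 (1.32 ± 0.05), Tacr3 (1.30 ± 0.05) and Npnt (1.23 ± 0.07). The largest falls were Trh (-1.53 ± 0.06), the cationic amino acid transporter gene Slc7a3 (-1.51 ± 0.05), Cstdc2 (-1.44 ± 0.07) and Epcam (-1.11 ± 0.07). All of these had limma adjusted p values of 1.1e-05 or less, and 1 direction in 4 of 4 pairs, as the naming rule required. As the mean of both days (4 arrays against 4), 2054 genes differed, 1094 higher and 960 lower, and 27 differed by at least 1. Median centring gave 838 higher and 1040 lower, so which direction has more genes rests on the scaling.

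Under MEF2C, 10 of 15 myofibroblast contractile genes rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 9.8e-13). Cnn1 was at 1.05, Myl9 at 0.99, Tagln at 0.97 and Acta2 at 0.65. Of 25 mesenchymal genes 11 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 5.6e-07), with Prrx2 at 0.63, Thy1 at 0.53 and the fibronectin gene Fn1 at 0.43. BMP response had 6 higher and 0 lower of 12 (7 and 0 adjusted over the list alone; camera adjusted p = 8.1e-06), with Id3, an inhibitor of basic helix-loop-helix factors, at 0.69. Extracellular matrix had 10 higher and 2 lower of 24 (10 and 5 adjusted over the list alone; camera adjusted p = 0.0027), led by Postn (1.12 ± 0.13) and Col5a2 (0.91 ± 0.06). With an estimated correlation the adjusted p was 0.026 for contractile genes, 0.034 for mesenchymal genes, 0.026 for BMP response and 0.049 for matrix. TGF-beta signalling had 10 higher and 0 lower of 19 (12 and 2 adjusted over the list alone; camera adjusted p = 2.2e-05, adjusted p = 0.12 with an estimated correlation), with Ltbp2 at 0.61 and Tgfb3 at 0.59.

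Cell cycle genes had 13 lower and 0 higher of 29 under MEF2C (19 and 0 adjusted over the list alone; camera adjusted p = 3.4e-13), with Cenpa at -0.40 and Ccna2 at -0.34. Interferon response had 8 lower and 0 higher of 22 (11 and 1 adjusted over the list alone; camera adjusted p = 3.6e-07), with Oasl2 at -0.60 and Oas2 at -0.49. Stress response had 3 higher and 0 lower of 16 (7 and 0 adjusted over the list alone; camera adjusted p = 7.3e-05), led by Atf3 at 0.45. With an estimated correlation the adjusted p was 0.026, 0.029 and 0.034 for these 3 lists. Epithelial genes had 7 lower and 0 higher of 29 (7 and 0 adjusted over the list alone; camera adjusted p = 0.0015, adjusted p = 0.20 with an estimated correlation), with Krt8 at -0.62 and Cdh1 at -0.47 beside Epcam. Pluripotency genes had 5 lower and 0 higher of 28 (5 and 0 adjusted over the list alone; camera adjusted p = 0.0087, adjusted p = 0.29 with an estimated correlation), with Tfcp2l1 at -0.64 and L1td1 at -0.49. Without SKO+Flag day 6 replicate 2 or day 10 replicate 1 the pluripotency camera adjusted p was 0.077 or 0.12. MEF2 targets and striated muscle genes had 3 higher and 1 lower of 32 (3 and 1 adjusted over the list alone), with Myom1 at 0.55 and Tnni1 at 0.44. Their camera adjusted p was 0.037, the adjusted p was 0.47 with an estimated correlation, and quantile normalization gave 0.058; the call was also lost without any 1 of 4 arrays. Hdac9 rose by 0.31 ± 0.05 in the class IIa HDAC and MEF2 family (2 higher, with Mef2c itself, and 0 lower of 7; 2 and 0 adjusted over the list alone; camera adjusted p = 0.90).

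At day 6 MEF2C changed 618 genes (266 higher, 352 lower), with Anxa10 at 1.65 and Trh at -1.31. At day 10 it changed 1397 (798 higher, 599 lower), with Anxa10 at 2.89, Tll1 at 1.70, Slc7a3 at -2.46 and Epcam at -1.68. Called at both days in 1 direction were 214 higher and 228 lower genes, against 10.6 and 10.6 for independent lists. At day 6, leaving out SKO+Flag replicate 1 or 2 of that day gave 244 or 268 genes, and leaving out SKO+MEF2C replicate 1 or 2 gave 157 or 227. At day 10, leaving out SKO+MEF2C replicate 1 or 2 gave 691 or 716, and fits to the compared groups alone called 351 genes at day 6 and 502 at day 10.

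**Figure D2:**
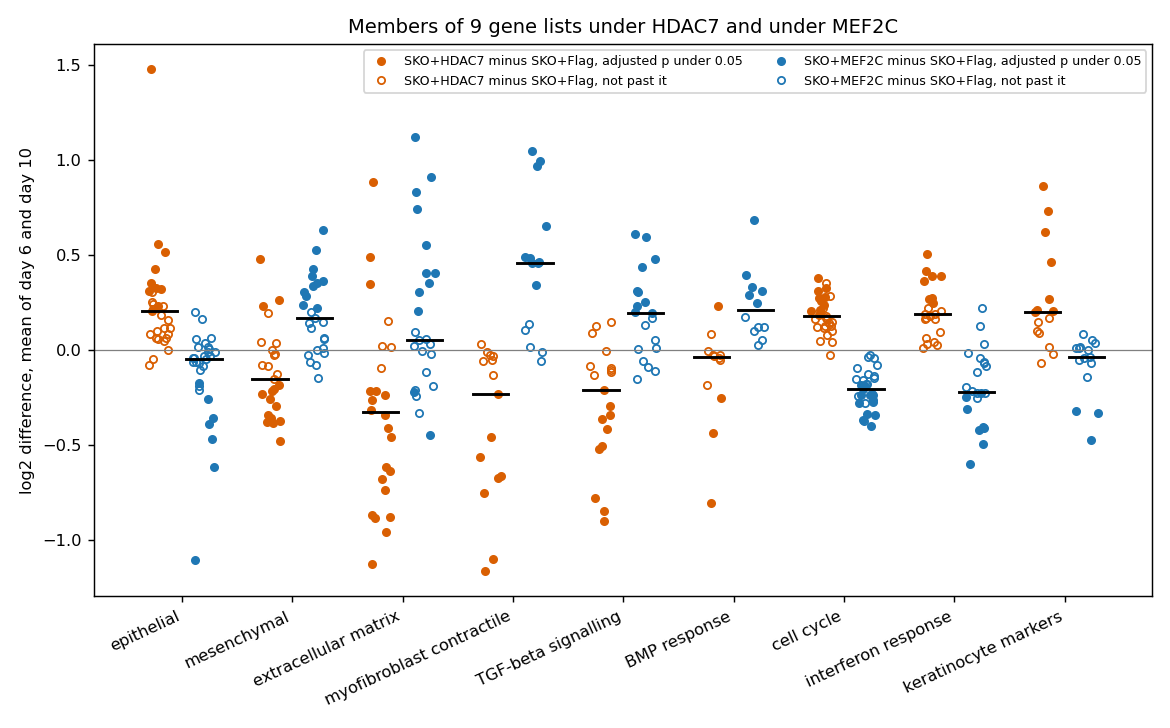
The log2 difference from SKO+Flag, mean of day 6 and day 10, of each measured member of 9 gene lists under HDAC7 (orange) and MEF2C (blue), with filled points for adjusted p under 0.05 and a line at the list's median. Medians lie at -0.23 for HDAC7 and 0.46 for MEF2C in the contractile list, and at 0.18 and -0.20 in the cell cycle list.

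SKO+HDAC7 and SKO+MEF2C differed from each other in 4395 genes (2051 higher and 2344 lower in SKO+HDAC7; 4 arrays against 4), 169 of them by at least 1. Cd34 (2.19 ± 0.06), Nefl (1.99 ± 0.09), Lpl (1.89 ± 0.08) and Krt19 (1.74 ± 0.05) were higher in SKO+HDAC7. Anxa10 (-3.04 ± 0.06), Akr1c14 (-2.99 ± 0.10), Col8a1 (-2.38 ± 0.08) and Npnt (-2.28 ± 0.07) were lower. Cell cycle genes were higher in SKO+HDAC7 for 25 of 29 members and lower for 0 (27 and 0 adjusted over the list alone), interferon response for 15 of 22 and 0 (16 and 0), epithelial genes for 13 of 29 and 0 (19 and 0) and keratinocyte markers for 8 of 15 and 0 (10 and 0). Lower in SKO+HDAC7 were 11 of 15 contractile genes with 0 higher (11 and 0 adjusted over the list alone), 16 of 24 matrix genes with 4 higher (16 and 5), 16 of 25 mesenchymal genes with 4 higher (17 and 4), 13 of 19 TGF-beta genes with 1 higher (13 and 1), 9 of 12 BMP genes with 1 higher (10 and 1) and 9 of 16 stress genes with 0 higher (12 and 0). Each of these 10 lists passed camera at the preset correlation and with an estimated one (adjusted p of 0.011 to 0.036). Pluripotency genes had 9 higher and 0 lower of 28 (9 and 0 adjusted over the list alone; camera adjusted p = 9.2e-05, adjusted p = 0.12 with an estimated correlation).

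Many genes that passed the test under both factors moved in opposite directions. Of 779 genes called in both comparisons with SKO+Flag, the transduced factors aside, 586 had opposite signs. Genes lowered by HDAC7 and raised by MEF2C numbered 356, against 66.3 for independent lists, and those raised by HDAC7 and lowered by MEF2C 230, against 46.4. Raised by both were 75 genes (52.8 for independent lists) and lowered by both 118 (58.2). Noise in the shared SKO+Flag arrays favours equal signs, so independent lists are too low a baseline for genes moved alike. Tagln and Akr1c14 fell under HDAC7 and rose under MEF2C, whereas Frem2 fell under both (-1.51 and -1.06). Across 19930 genes, which are not independent replicates, the effects had a Pearson correlation of -0.18 and a Spearman correlation of 0.036, which differ in sign. Both effects use the same SKO+Flag arrays: unchanged groups simulated against shared controls gave a Pearson correlation of 0.50, with a covariance of 0.0019. The observed covariance was -0.0043. No such value is at hand for the Spearman correlation, so it cannot show which genes the negative sign rests on. With a different SKO+Flag experiment as control for each effect the Pearson correlation was -0.27 or -0.25. Leaving out SKO+Flag day 6 replicate 2 or day 10 replicate 1 gave -0.083 or -0.044.

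**Figure D3:**
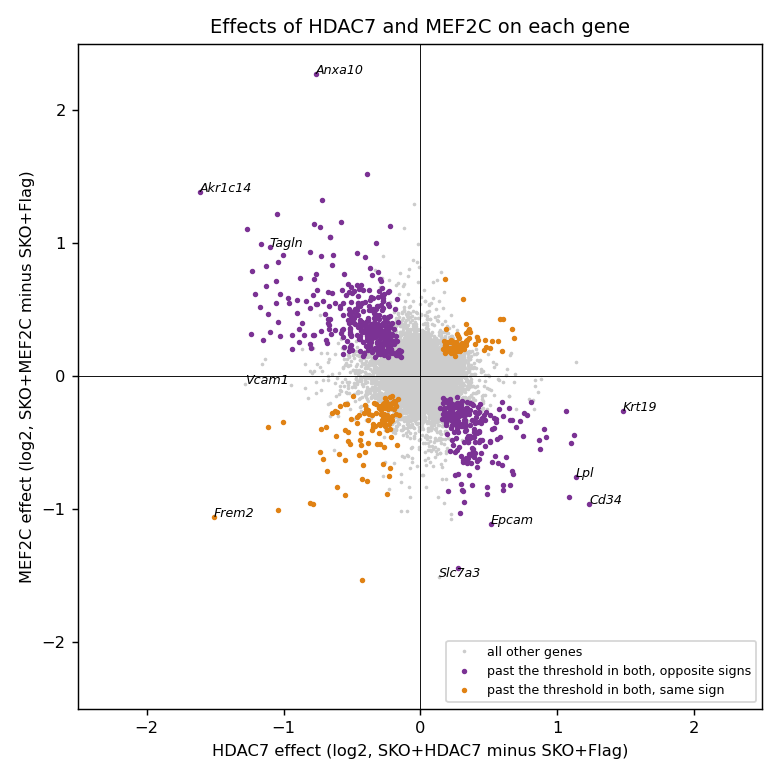
The log2 effect of HDAC7 (horizontal) and of MEF2C (vertical) on each gene, the transduced factors left out, as the mean of both days. Of the 779 genes past the threshold in both, the 586 with opposite signs are purple and the others orange, and a grey cloud of all other genes is centred near 0.

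From day 6 to day 10 SKO+Flag cells gained interferon genes and lost contractile genes. Slc7a3 rose by 2.97 ± 0.07, Epcam by 2.36 ± 0.10, Cstdc2 by 2.30 ± 0.10 and Trh by 1.75 ± 0.09. Anxa10 (-2.02 ± 0.08), the calponin gene Cnn1 (-1.49 ± 0.09), Tagln (-1.35 ± 0.07) and Stc1 (-1.32 ± 0.08) fell. All of these had limma adjusted p values of 7.4e-06 or less, and 1 direction in 2 of 2 pairs, as the naming rule required. In all, 1610 genes changed (747 higher and 863 lower, 2 arrays against 2), 78 of them by at least 1. GFP cells were not compared between the days, so time in culture is not separated from the course under SKO. Leaving out SKO+Flag day 6 replicate 2 gave 944 genes, and a fit to the SKO+Flag arrays alone called 504.

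Of 15 contractile genes 12 fell with time in SKO+Flag and 0 rose (13 and 0 adjusted over the list alone; camera adjusted p = 3.8e-17, adjusted p = 0.013 with an estimated correlation). Interferon response had 10 higher and 0 lower of 22 (14 and 0 adjusted over the list alone; camera adjusted p = 9.4e-13, adjusted p = 0.013 with an estimated correlation), led by Gbp3 (1.14) and Oasl2 (0.97). Epithelial genes had 8 higher and 0 lower of 29 (10 and 1 adjusted over the list alone; camera adjusted p = 2.5e-08, adjusted p = 0.061 with an estimated correlation), with the protease gene St14 at 1.08. Keratinocyte markers had 5 higher and 0 lower of 15 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00038, adjusted p = 0.064 with an estimated correlation), with Lgals7 at 0.92. Mesenchymal genes had 12 lower and 1 higher of 25 (15 and 1 adjusted over the list alone; camera adjusted p = 1.4e-07, adjusted p = 0.051 with an estimated correlation), with Cdh2 at -0.77 and Snai2 at -0.61. Extracellular matrix had 9 lower and 4 higher of 24 (11 and 5 adjusted over the list alone; camera adjusted p = 0.0017, adjusted p = 0.057 with an estimated correlation), with Lox at -0.92 and the elastin gene Eln at 1.14. BMP response had 3 lower and 0 higher of 12 (3 and 0 adjusted over the list alone; camera adjusted p = 0.0013, adjusted p = 0.054 with an estimated correlation). Pluripotency genes had 6 higher and 0 lower of 28 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0027, adjusted p = 0.20 with an estimated correlation), led by Tfcp2l1 (1.15). Without SKO+Flag day 6 replicate 1 or day 10 replicate 1 the pluripotency camera adjusted p was 0.068 or 0.082, and its median lay below 0 in both. Cell cycle genes had 5 lower and 0 higher of 29 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00014, adjusted p = 0.11 with an estimated correlation), with Rrm2 at -0.34.

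In SKO+HDAC7 2902 genes changed between the days (1567 higher, 1335 lower), with Epcam at 2.95, Aqp3 at 2.31 and Anxa10 at -2.86. Epithelial genes had 17 higher and 0 lower of 29 there (17 and 0 adjusted over the list alone; camera adjusted p = 2.7e-13, adjusted p = 0.022 with an estimated correlation). In SKO+MEF2C 614 genes changed (369 higher, 245 lower), with Cd34 at 1.53 and Fhl1 at -1.01, and contractile genes had 9 lower and 0 higher of 15 (12 and 0 adjusted over the list alone; camera adjusted p = 2.4e-16, adjusted p = 0.029 with an estimated correlation). Genes called in SKO+Flag and in SKO+HDAC7 in 1 direction numbered 535 higher and 594 lower (58.7 and 57.8 for independent lists), and 287 higher and 199 lower in SKO+Flag and SKO+MEF2C (13.8 and 10.6). Leaving out SKO+HDAC7 day 6 replicate 1 or day 10 replicate 2 gave 1666 or 1571 genes in SKO+HDAC7. In SKO+MEF2C, leaving out day 6 replicate 1 or 2 gave 317 or 272, leaving out day 10 replicate 1 or 2 gave 283 or 250, and array weights gave 994.

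The effect of HDAC7 differed between day 6 and day 10 for 25 genes (8 more positive at day 10, 17 more negative; 2372 at an unadjusted p under 0.05), and that of MEF2C for 17 (9 and 8; 1337 unadjusted). Ltf, which encodes lactotransferrin, shifted by 1.08 ± 0.14 and Vegfd by -1.03 ± 0.09 for HDAC7. Slc7a3 shifted by -1.90 ± 0.10, Epcam by -1.15 ± 0.14 and Anxa10 by 1.24 ± 0.11 for MEF2C. Extracellular matrix was the list whose HDAC7 effect differed between days with an estimated correlation too (median shift -0.27; 4 lower and 0 higher of 24, 12 and 1 adjusted over the list alone; adjusted p = 0.0097). Median centring gave 9 and 9 genes for HDAC7 and 6 and 11 for MEF2C, in the order more positive and more negative. The HDAC7 count rests on single arrays. It was 8 or 7 without SKO+Flag day 6 replicate 1 or 2, 483 without SKO+Flag day 10 replicate 2, 3 or 13 without SKO+HDAC7 day 6 replicate 1 or 2, 11 or 0 without SKO+HDAC7 day 10 replicate 1 or 2, 15 without either SKO+MEF2C day 6 replicate and 16 without either SKO+MEF2C day 10 replicate (limma). The MEF2C count was 6 or 3 without SKO+Flag day 6 replicate 1 or 2, 213 without SKO+Flag day 10 replicate 2, 9 without either SKO+HDAC7 day 6 replicate, 4 or 2 without SKO+MEF2C day 6 replicate 1 or 2, and 4 or 7 without SKO+MEF2C day 10 replicate 1 or 2.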

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

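The tests of separate controls, of the MEF2C correlation taken alone, of a lower SKO share as the whole cause and of the Sox2 and Klf4 probes were chosen after the results were seen. The requirement that a bound be passed by more than the SD over left-out arrays was also applied after the values were seen. The first pattern had 3 tests, the second 5 and the third 1.

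The effects of HDAC7 and MEF2C on 25 and 17 genes differed between the days by the interaction test. For HDAC7 the effect was more positive at day 10 for Ltf (1.08), Pcx (1.08), Ehf (1.02), Itgam (0.97) and Gbp4 (0.96). It was more negative for Vegfd (-1.03), Dkk2 (-0.85), Anxa10 (-0.84), Mgp (-0.82) and Fbln5 (-0.81). Extracellular matrix genes had a median shift of -0.27. For MEF2C the effect was more positive at day 10 for Anxa10 (1.24), Tll1 (1.13), Tslp (0.89), Gnai1 (0.78) and Mest (0.77). It was more negative for Slc7a3 (-1.90), Epcam (-1.15), Cstdc2 (-1.11), Ildr1 (-1.10) and Slc17a6 (-1.05). The number of such genes rests on single arrays: it was 0 for HDAC7 without SKO+HDAC7 day 10 replicate 2, 483 without SKO+Flag day 10 replicate 2, and for MEF2C 2 without SKO+MEF2C day 6 replicate 2 and 213 without SKO+Flag day 10 replicate 2.

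Of 779 genes called under both HDAC7 and MEF2C, 586 had opposite signs. Over all genes 44.4% did, and the Spearman correlation was 0.036. Values for unchanged groups with shared controls are not given for either, so they cannot show opposite effects. In simulation shared controls alone gave a Pearson correlation of 0.50, which favours equal signs. Thus neither value argues against opposite effects. The Pearson correlation was -0.18, and -0.083 or -0.044 without SKO+Flag day 6 replicate 2 or day 10 replicate 1. Shared SKO+Flag arrays alone argue for a positive value, and with a different SKO+Flag experiment for each effect the higher of the correlations was -0.25. Quantile normalization gave a Pearson correlation of -0.20, so the differences in intensity distribution that it removes do not account for the value of -0.18. Opposite shifts along the course from day 6 to day 10 stay open: with the day effect in SKO+Flag removed the correlation was -0.12, past the bound of -0.1 set beforehand, which alone would have argued against them, but by less than its SD over left-out arrays (0.046), and it was 0.0030 without SKO+Flag day 6 replicate 2. Opposed actions of the 2 factors on the same genes remain a hypothesis.

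The MEF2C effect ran against the day effect in SKO+Flag across genes (correlation -0.48; -0.54 to -0.36 with 1 array left out) and the HDAC7 effect along it (0.16; 0.0098 to 0.24). With day effects from other arrays the correlations were -0.40 and 0.042. In 0 of 100 simulated sets of unchanged groups was the difference between both correlations as large. The simulation drew genes independently, and the day effect apart from the other arrays, so it cannot show what noise shared across genes would give. The prediction made beforehand asked for over 0.2 for HDAC7 and under -0.2 for MEF2C together, which 0.16 neither met nor excluded, whereas the correlation for MEF2C alone is consistent with a shift against the day course. For a lower share of cells carrying SKO under MEF2C, the bound set beforehand was met. The median of 29 genes raised at least 8-fold by SKO was -0.40 (95% bootstrap interval -0.61 to -0.25). The SKO-lowered genes implied -0.054. That bound takes any larger fall as met, so it cannot decide whether a lower share contributes. Implied shares of cells without SKO also differed, 4.0% from the SKO-lowered and 24.1% from the SKO-raised genes. Pou5f1, which is not among these genes, was at -0.14 ± 0.05 under MEF2C (limma adjusted p = 0.15), higher in 0 of 4 pairs. Its difference did not pass the test, so this 1 gene does not settle the share. As the whole cause a lower share is argued against by a test set later. If cells without SKO resemble the GFP arrays, the fall of the raised genes implies a rise of 0.96 in 43 genes lowered at least 4-fold by SKO. Their median rise was 0.21 (0.15 to 0.32). Both bootstrap intervals resample genes, not arrays, so they hold no spread between arrays or cultures.

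As the mean of both days Sox2 and Klf4 did not pass the test between SKO+Flag and GFP while Pou5f1 was at least 108-fold higher; at day 10, against 1 GFP array, Klf4 passed with a difference of 0.32. That Klf4 difference rests on a GFP value of 8.66 at day 10, against 8.93 on the GFP array of day 6. For Sox2 and Klf4, probes that lie outside the transduced sequence are a candidate explanation. The Sox2 difference of 0.16 cannot decide it, because the positions of the probes were not used here. No biological explanation was tested.

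The 8 arrays of a comparison can be split into 4 and 4 in 35 ways. Day was a covariate in every fit but that of the split by day itself, which cannot hold it and so counts differences between the days. For MEF2C against SKO+Flag the real split gave 1676 genes, the split by day 487, the highest other, and every remaining split 0. Thus 1 of the 35 gave as many, a share under the bound set beforehand and the smallest that 35 splits can give. For HDAC7 against MEF2C the real split gave 3932, the split by day 100, again the highest other, and every remaining split 0. Here too 1 of the 35 gave as many. For HDAC7 against SKO+Flag the real split gave 1387 genes and 2 of the 35 gave as many, a share over the bound set beforehand. The excess rests on the split by day alone, with 1508 genes from a fit of another form. Every split fitted with day other than the real one gave 0, so the share does not set HDAC7 apart from MEF2C. Splits that mix the vectors put any vector difference into the spread, which lowers their counts. As replicate arrays may be technical, the splits cannot decide whether separate cultures of 1 vector would differ as much. Within the days HDAC7 against SKO+Flag called 914 genes at day 6 and 1450 at day 10.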

How the results depend on the processing

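All alternatives but the block with crossed numbers were chosen before the data were examined. With 1 array left out, 179 of 220 results stayed within 1.5 times the reported value, or within its spread, and with other alternatives 123 of 157. No called named gene changed sign, and no called list changed the direction of its camera test, under any alternative that was run. List medians near 0 did change sign with 1 array left out, for pluripotency, glycolysis and keratinocyte markers with the day in SKO+Flag, for keratinocyte markers under MEF2C and for pluripotency in the MEF2C effect by day. Among genes above the median level the pluripotency median under SKO lay above 0 (0.57), and median centring turned which direction had more genes under MEF2C. Named genes lost their call in 330 of 7396 comparisons with 1 array left out and in 127 of 4932 with other alternatives. Lists lost it in 51 of 2112 and 12 of 1218. Leaving out the only GFP array of a day gives no value for the SKO comparisons that need it. The cause was not tested except where fewer genes or arrays enter by construction. Dim genes have little signal over background, and no detection calls were used here.

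A difference of at least 1 left 37 (HDAC7), 21 (day 6), 62 (day 10), 27 (MEF2C), 14 (day 6), 55 (day 10), 903 (SKO), 793 (day 6), 1137 (day 10), 78 (day in SKO+Flag), 159 (in SKO+HDAC7), 24 (in SKO+MEF2C), 4 and 8 (HDAC7 and MEF2C by day) and 169 (HDAC7 against MEF2C). Only the arrays of the compared groups, with fewer degrees of freedom, gave 375 and 501 (HDAC7 at day 6 and 10), 351 and 502 (MEF2C), 3012 (SKO at day 10), 504 (day in SKO+Flag), and 2 and 1 (HDAC7 and MEF2C by day). The change of the HDAC7 effect between days had 66 genes with a robust prior, 63 after quantile normalization, 69 among genes above the median level and 16 with array weights. That of MEF2C had 44 with a robust prior and 45 among genes above the median level. Array weights gave 994 for the day in SKO+MEF2C. The correlation of the effects was -0.26 among genes above the median level.

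Groups share experiment numbers, but the deviations of same-numbered arrays correlated from -0.24 to 0.18 over 15 pairs of groups, over 0.1 in 4, so the numbers were not taken to pair the arrays. The replicate block gave 15 genes for the HDAC7 effect by day, and the block per day 15 for it and 11 for MEF2C. Other counts stayed within 1.5 times, with 2152 genes for HDAC7 and 2007 for MEF2C. A block with the SKO+Flag day 6 numbers crossed, chosen after seeing the data, gave 1693 genes for the day in SKO+Flag.

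With 1 array left out, counts ranged from 1469 to 2404 (HDAC7), 293 to 1266 (day 6), 785 to 1484 (day 10), 1381 to 2148 (MEF2C), 157 to 772 (day 6), 691 to 1421 (day 10), 6367 to 7550 (SKO), 3753 to 5223 (day 6), 4652 to 5584 (day 10), 944 to 1905 (day in SKO+Flag), 1571 to 3367 (in SKO+HDAC7), 250 to 739 (in SKO+MEF2C), 0 to 483 (HDAC7 by day), 2 to 213 (MEF2C by day) and 3342 to 4781 (HDAC7 against MEF2C). The correlation ranged from -0.22 to -0.044. The lone array that remains in a group is then assumed to vary like the other groups.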

Other observations

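The tests of how the effects correlate with the SKO effect, below, were chosen after the results were seen. Single markers of other cell types stood apart from their lists between SKO+Flag and GFP. Among macrophage and blood markers Laptm5 rose by 2.89 ± 0.07 and Itgam by 1.00 ± 0.06, with 3 higher and 5 lower of 17 (3 and 6 adjusted over the list alone; camera adjusted p = 0.80; median -0.11, mean 0.13). Among endothelial markers Tek rose by 2.78 ± 0.08, and the other called members fell (1 higher and 3 lower of 14, 1 and 3 adjusted over the list alone; camera adjusted p = 0.35; median -0.08, mean 0.03). The neuronal gene Stmn2 rose by 3.10 ± 0.05 and Map2 fell by 1.06 among neural and glial markers (4 higher and 2 lower of 16, 5 and 3 adjusted over the list alone; camera adjusted p = 0.22). Keratinocyte markers had 6 higher and 0 lower of 15 (6 and 0 adjusted over the list alone; camera adjusted p = 0.13), endoderm and trophoblast markers 1 higher and 4 lower of 18 (1 and 4 adjusted over the list alone; camera adjusted p = 0.21), and fat and cartilage markers 3 higher and 9 lower of 17 (3 and 9 adjusted over the list alone; camera adjusted p = 0.14), with Cd36 at 2.49 and Sox9 at -0.87. Inflammatory and secreted genes had 5 higher and 10 lower of 21 (6 and 10 adjusted over the list alone; camera adjusted p = 0.26), with Cxcl12 at -2.52 and Vcam1 at 2.00. Glycolysis genes had 4 higher and 8 lower of 13 (4 and 8 adjusted over the list alone; camera adjusted p = 0.19), interferon response genes 4 higher and 10 lower of 22 (5 and 10 adjusted over the list alone; camera adjusted p = 0.14), and MEF2 targets and striated muscle genes 3 higher and 9 lower of 32 (3 and 9 adjusted over the list alone; camera adjusted p = 0.21).

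Smaller lists passed camera at the preset correlation but not with an estimated one. Under HDAC7 endoderm and trophoblast markers had 2 higher and 0 lower of 18 (2 and 0 adjusted over the list alone; camera adjusted p = 0.048, adjusted p = 0.40 with an estimated correlation). Under MEF2C glycolysis genes had 3 higher and 0 lower of 13 (6 and 0 adjusted over the list alone; camera adjusted p = 0.0061, adjusted p = 0.20 with an estimated correlation), with the phosphofructokinase gene Pfkp at 0.43. Keratinocyte markers had 3 lower and 0 higher of 15 there (3 and 0 adjusted over the list alone; camera adjusted p = 0.023, adjusted p = 0.20 with an estimated correlation), and fat and cartilage markers 4 higher and 1 lower of 17 (4 and 1 adjusted over the list alone; camera adjusted p = 0.026, adjusted p = 0.37 with an estimated correlation), with the cartilage genes Col10a1 at 0.86 and Acan at 0.81. With time in SKO+Flag, p53 and senescence genes had 7 lower and 1 higher of 18 (7 and 1 adjusted over the list alone; camera adjusted p = 0.015, adjusted p = 0.14 with an estimated correlation), with Ccng1 at -0.73 and Mdm2 at -0.54. Stress response had 4 lower and 0 higher of 16 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0090, adjusted p = 0.11 with an estimated correlation), with the asparagine synthetase gene Asns at -0.87. Glycolysis had 4 higher and 0 lower of 13 (4 and 0 adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.21 with an estimated correlation), with Aldoc at 1.39. Macrophage and blood markers had 2 lower and 1 higher of 17 (4 and 1 adjusted over the list alone; camera adjusted p = 0.038, adjusted p = 0.11 with an estimated correlation), with Itgam at -0.70.

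Some genes of lists that did not pass as a whole changed with the added factors. Cd68 (0.63 ± 0.07), Tek (0.60 ± 0.06), the chemokine gene Ccl2 (0.87 ± 0.06) and the glucose transporter gene Slc2a1 (0.61 ± 0.05) rose under HDAC7, and the fatty acid transporter gene Cd36 fell by 1.17. Laptm5 (-0.69 ± 0.06), Tek (-0.67 ± 0.06), Nefl (-0.91 ± 0.09) and Ccl2 (-0.55 ± 0.06) fell under MEF2C. The MEF2C effect and the SKO effect had a correlation of -0.41 across genes, and the HDAC7 effect and the SKO effect -0.090. Both effects share the SKO+Flag arrays: the covariance was -0.028 for MEF2C and -0.0063 for HDAC7, against -0.0019 for simulated unchanged groups with the same shared arrays. Those simulated groups had a correlation of -0.41, which holds noise alone and no SKO effect, so it is not on the scale of the observed correlations and the covariances are the values to compare. With a different SKO+Flag experiment in each effect the correlations were -0.39 and -0.33 for MEF2C and -0.076 and -0.032 for HDAC7.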
